A study of Caenorhabditis elegans with 2 samples.

How the data were processed

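ChIP-seq for eGFP-tagged LSY-2 was carried out on mixed-stage *C. elegans* embryos, with 2 biological replicates in 1 group. The labels name lsy-2 as the antibody target and call the replicates biological, and p-values here describe peaks, genes or windows, never the spread between animals. The authors deposited 4 peak lists for each of 2 builds, ce11 and ce10: a list per replicate, a pooled list, and the list that passed their IDR threshold, which per the deposited metadata derives from the pooled and replicate lists. The aligner, peak caller, versions and IDR threshold are not given in the sources used here. Per the deposited metadata, each list of 30000 peaks also drew on a further file that the metadata do not describe. The labels name possible controls, which were not used here.

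Each peak carries the authors' signal value, whose scale is set within a list, so it served only to rank and describe peaks of 1 list. The deposited lists also give a −log10 q-value, which ran from 2.32 to 2.79 in the IDR list and was not used for ranking, and the offset of the summit from the peak start, which is in bp. The authors' peaks had mostly fixed lengths: 68.3% of IDR peaks were 380 bp long, with the summit at the midpoint in 68.5%. The 2568 IDR peaks on ce11 were the 2568 highest-signal peaks of the pooled list. Read numbers per sample were not analysed here, so the depth is unknown and no interval that needs it is given. Per the deposited metadata the lists of 30000 peaks hold peaks and background, so their length was not read as a number of bound regions.

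Coordinates are on ce11. The reference used was WBcel235 with Ensembl annotation release 115, and every ce11 peak ended within its chromosomes' lengths. Only the replicate overlap and rank correlation were repeated on ce10, within that build. Genes were keyed by identifier, because some symbols are shared by several genes, as for 36 of the 72 histone genes. The gene lsy-6 was located from RefSeq gene coordinates of the same assembly. Operons were not treated separately.

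A summit was assigned to a promoter window 1000 bp upstream to 300 bp downstream of any protein-coding 5' end, otherwise to an exon, an intron or elsewhere. Shares have 95% Wilson intervals. Positions were tested by circular permutation, with 10000 rotations of all summits along each chromosome, two-sided, for which the smallest p is 0.0002, since the smaller tail was doubled, as it was for the median ranks. Reciprocal overlap used 200 rotations, and the comparison of all peaks and the reverse direction used 1000. Gene lists were tested with Fisher's exact test and Benjamini-Hochberg adjustment over 22 lists, with exact intervals of the odds ratio. The X share was tested with an exact binomial test, GC content, in windows reaching 50 bp to each side of the summit, with 100000 permutations counted on the absolute difference, and 2080 6-mers (each joined with its reverse complement) with Fisher's exact test and adjustment. Control windows lay at the same signed distance from the outermost 5' end of random genes without a summit.

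Genes named were chosen by a rule fixed before the data were examined: lsy-2, unc-119 and every ASE gene; the nearest gene of the 20 highest-signal peaks; up to 4 members of each list past the threshold and up to 2 of each other list, by peak signal; and the 5 hexamers (6-mers) of largest odds ratio among those past an adjusted p of 0.05 and in at least 5% of summit windows. The genes F49H12.3 and F53B1.3, and partners named beside a peak, were added after the values were seen.

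Alternatives were the 1284 IDR peaks of highest signal, the top of the pooled list without an IDR threshold, the top peaks of each replicate alone, peak midpoints, other promoter windows, distances and sequence windows, a logistic model with distance to the upstream gene, rotations for gene lists, GC-matched controls (the nearest in GC of 20 candidates) and the ce10 lists. Merging overlapping peaks, leaving out mitochondrial peaks or soft-masked summits, a logistic model with promoter GC, and rotations on the share of genes with a summit were added after seeing the data.

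The tests were checked on simulated peaks. With promoter summits planted among 2500, the promoter share recovered was 71.7% against an expected 71.0%. That expectation included the share the same method gave for random summits, so it is not independent of the method. The list of 28 Wnt genes, with summits planted at 23, was called with 0 others. Random summits gave 0 called lists of 22. A planted 6-mer ranked 1 of 2080 by p, with 1 other called. Both sets of windows there were random positions, so a difference in GC content like that of the data was not simulated. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.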

Results

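LSY-2 is a C2H2 zinc finger transcription factor of the nematode *Caenorhabditis elegans* that is known for its part in the left/right asymmetry of the ASE taste neurons. Its genome-wide binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mixed-stage embryos of strain OP367, whose integrated transgene expresses LSY-2 fused to enhanced green fluorescent protein (eGFP). The samples formed 1 group of 2 biological replicates of whole animals of both sexes, with no comparison group. Each replicate was represented by a list of 30000 peaks, and the pooled replicates by a further list of 30000 peaks and by 2568 peaks that passed the authors' threshold on the irreproducible discovery rate (IDR), all on genome build ce11. Read depth per sample is unknown from these lists, so intervals on shares are 95% Wilson intervals that cover only the sampling of peaks or genes. The signal value of a peak is the authors' own and was used only to rank or describe peaks within a list.

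The strongest LSY-2 peaks included several upstream of ribosomal protein genes. The highest signal, 5501, belonged to a peak on chromosome III from 3867278 to 3867835, whose summit lay at -290 bp from the 5' end of *rpl-3* (WBGene00004414), a large ribosomal subunit protein gene. The next peak, with a signal of 5475 on chromosome IV from 4749790 to 4750352, lay upstream of Y17G9B.5 and *rpl-20*, and the peak of rank 3, with a signal of 4114 on chromosome IV from 654683 to 655175, lay upstream of *rpl-15*. Ranks 4 to 6 were held by peaks upstream of *cox-5A*, a cytochrome c oxidase subunit gene, of *rps-1*, a small ribosomal subunit protein gene, and of *ekl-4*, with signals of 3419, 3360 and 3227. The other peaks among the 20 highest had as their nearest 5' ends Y55F3AR.2, *nra-2*, *mig-5*, *cap-2*, *ndub-8*, *rfc-4*, *serp-1.1*, Y25C1A.8, *elof-1*, F55A11.1, *wdr-46*, *sec-24.1*, *pdtf-1* and *rpl-6*, with signals from 2544 down to 1826. All 20 summits fell in a promoter window, defined as 1000 bp upstream to 300 bp downstream of an annotated protein-coding 5' end, and all 20 peaks ranked 21 or better in both replicates. Several of these summits also lay in the promoter window of another gene, so the nearest gene is not an assigned target. Among such genes were *rps-20* at rank 6, *cct-8* at rank 7, *lin-53* at rank 8, *cct-1* at rank 9 and *eef-1A.1* at rank 12.

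The first comparison asked how far both replicates found the same regions. Of the 2568 highest-signal peaks of replicate 1, 1911 overlapped one of the 2568 highest-signal peaks of replicate 2 by at least 1 bp, or 74.4% (95% interval 72.7 to 76.1). Circular permutation, in which the replicate 2 peaks were rotated along each chromosome, gave a mean of 2.57% (two-sided p = 0.0002, the smallest that 10000 rotations can give). In the reverse direction the share was 74.1%. Among the 642 IDR peaks with the highest signal, such as those at *rpl-3* and *lsy-2*, 640 lay among the top 2568 of both replicates, against 130 of the 642 with the lowest signal. The IDR peaks were ranked in the list pooled from both replicates, and those of lowest signal lay nearest the cutoff of 2568. That contrast is therefore largely set by how the peaks were chosen. Across 2557 IDR peaks that overlapped a peak in each replicate, the replicate signals had a Spearman correlation of 0.680. It was computed across peaks, which are not independent replicates and were themselves chosen for strength in the pooled replicates. With all 30000 peaks of each list, the overlap was 45.4% against 19.95% for rotated peaks.

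**Figure D1:**
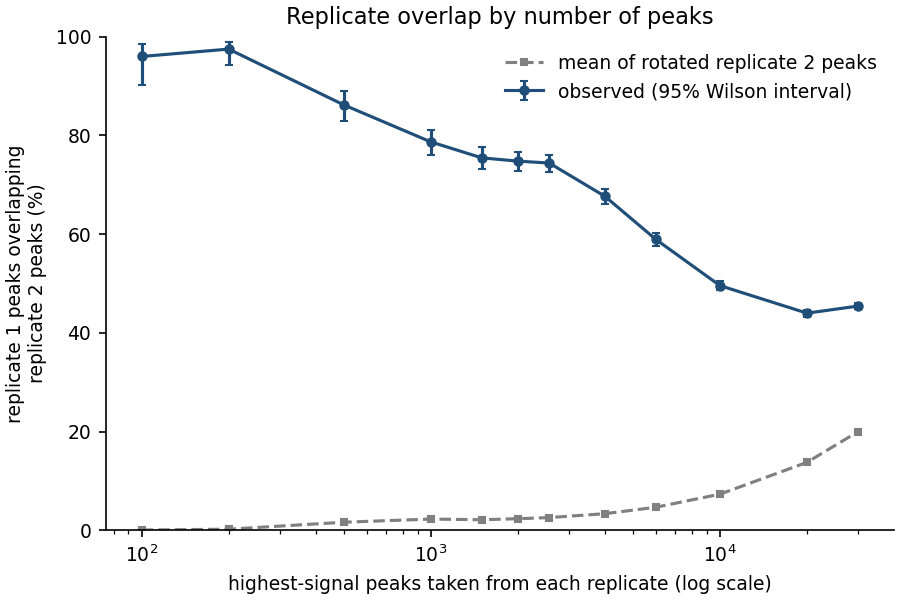
Percent of replicate 1 peaks that overlap a replicate 2 peak (y axis) against the number of highest-signal peaks taken from each replicate (x axis, log scale), with 95% Wilson intervals and, as squares, the mean of 50 rotations. The share was 96.0% for the top 100 peaks, 74.4% for the top 2568 and 45.4% for all 30000.

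The second comparison asked where in the genome the summits lay. Promoter windows held 1828 of the 2568 IDR summits, or 71.2% (69.4 to 72.9), against 28.2% for rotated summits (two-sided circular permutation p = 0.0002, the smallest that 10000 rotations can give). Protein-coding exons outside these windows held 25 summits, or 0.974% (0.660 to 1.43), against 21.1% for rotated summits, introns held 12.1% against 27.2%, and all other sequence 15.7% against 23.5% (permutation p = 0.0002 for each). Summits in nuclear promoter windows had a median position of -176 bp from the nearest 5' end, and 93.2% of the 1813 lay upstream. The window reaches 1000 bp upstream but 300 bp downstream, so most evenly placed summits would also lie upstream. No expected share was computed. The promoter share was 83.8% among the 642 peaks with the highest signal and 57.0% among the 642 with the lowest, while the intron share was 4.98% and 18.5%. Many worm 5' ends are trans-splice sites, so the start of transcription can lie further upstream. With a window of 500 bp upstream to 100 bp downstream, the exon share was 2.10%.

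**Figure D2:**
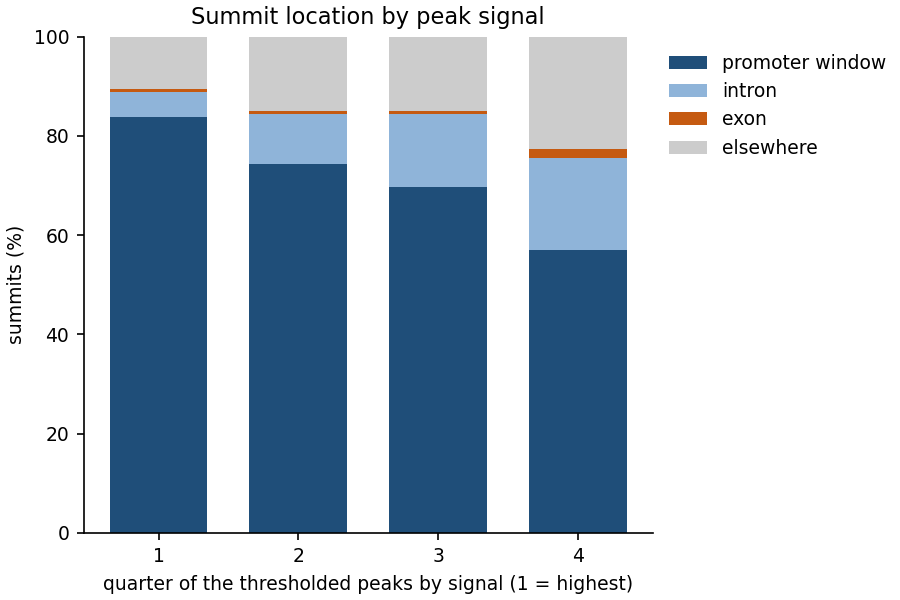
Stacked bars give the percent of summits (y axis) in promoter windows, introns, exons and elsewhere, for each group of 642 IDR peaks ordered by signal (x axis, 1 the highest). The promoter share was 83.8% in the group of highest signal and 57.0% in the group of lowest signal.

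At the level of genes, 2519 of 19985 protein-coding genes (12.6%) had an IDR summit in a promoter window, against a mean of 773 for rotated summits (two-sided permutation p = 0.0002, the smallest that 10000 rotations can give). Chromosomes I and III had the highest shares of nuclear genes with a summit, 20.4% (18.9 to 21.9) and 20.9% (19.4 to 22.5). Chromosomes V and X had the lowest, 7.01% (6.33 to 7.75) and 6.55% (5.69 to 7.54), and each of these 4 chromosomes differed from the rest of the genome by Fisher's exact test (largest adjusted p = 6.79e-28). Chromosomes II, at 12.9%, and IV, at 12.1%, did not (adjusted exact p = 0.535 and 0.383). The X chromosome held 268 of 2550 nuclear peaks, or 10.5% (9.38 to 11.8), below its 13.7% of nuclear protein-coding genes (exact binomial test, two-sided, p = 1.67e-06). Of the 1828 promoter summits, 742 lay in the windows of 2 or more genes. With the 1284 IDR peaks of highest signal the number of genes was 1468.

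The third comparison set 22 gene lists, fixed before the data were examined, against all other protein-coding genes. No control sample was used here, so signal common to active promoters in any immunoprecipitation was not tested. Lists past the threshold, enriched or depleted, are thus not shown to be particular to LSY-2. Cytosolic ribosomal protein genes had the highest share, with a summit at 71 of 79 genes (89.9%, 81.3 to 94.8; odds ratio 63.3, 30.4 to 152; adjusted p = 5.86e-54 by two-sided Fisher's exact test), led by *rpl-3*, *rpl-20*, *rpl-15* and *rps-1*. Proteasome genes followed with 27 of 33 (odds ratio 31.5, 12.7 to 93.5; adjusted exact p = 1.72e-18), led by *rpn-5*, *pas-4*, *rpn-6.1* and *rpn-13*, with signals of 1608, 1541, 1104 and 1019. Synthetic multivulva class B (synMuv B), DREAM complex and MES chromatin genes had 15 of 29 (odds ratio 7.47, 3.36 to 16.7; adjusted exact p = 1.54e-06), among them the DREAM subunit genes *lin-53*, *lin-9* and *lin-54* at ranks 8, 32 and 207 and the chromodomain gene *mrg-1* at rank 349. The *lin-53* peak is shared with *nra-2*, whose 5' end is nearer to the summit. Homeobox genes had 22 of 94 (odds ratio 2.13, 1.254 to 3.479; adjusted exact p = 0.0105), with *unc-62*, *ceh-6*, *ceh-38* and *nob-1* at ranks 249, 255, 259 and 286. The median peak rank of ribosomal protein genes with a summit was 208, against 1053 for all genes with a summit (permutation test, two-sided, adjusted p = 0.00012 over 6 lists with at least 10 such genes, from p = 2.0e-05, the smallest that 100000 permutations can give with the smaller tail doubled), and no other of these lists passed. The homeobox call ended with the 1284 peaks of highest signal (odds ratio 1.85, adjusted exact p = 0.153), with the shorter promoter window of 500 bp upstream to 100 bp downstream (1.77, p = 0.0932), and as a share of genes with a summit (ratio to rotated summits 1.69, adjusted permutation p = 0.449). With summits in soft-masked (repeat or low-complexity) sequence left out, the odds ratio was 26.9 for ribosomal protein genes and 13.7 for proteasome genes, and with the 1284 peaks it was 17.3 for proteasome genes.

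Members of 5 large gene families had summits less often than other genes. Chemoreceptor genes had 7 of 1308 (0.535%; odds ratio 0.0346, 0.0139 to 0.0717; adjusted exact p = 5.77e-66), of which *srh-16*, *sri-5*, *sre-23* and *sre-1* had the highest signals, from 154 to 76.1. C-type lectin genes had 4 of 240 (odds ratio 0.116; adjusted exact p = 3.97e-09), namely *clec-53*, *clec-87*, *clec-126* and *clec-140*. F-box genes had 9 of 322 (odds ratio 0.197; adjusted exact p = 3.07e-09), led by *fbxc-23*, *fbxb-85*, *fbxa-90* and *fbxa-145*. Nuclear hormone receptor genes had 12 of 274 (odds ratio 0.314; adjusted exact p = 1.72e-05), led by *nhr-49*, *nhr-47*, *nhr-142* and *nhr-25*. Collagen genes, which encode cuticle proteins, had 8 of 175 (odds ratio 0.330; adjusted exact p = 0.00145), led by *col-38*, *col-2*, *dpy-14* and *col-8*, and the peak at *col-2* overlapped no replicate 2 peak. Counted against rotated summits, members of all these lists but the chemoreceptors lost the call (adjusted permutation p = 0.416 for C-type lectins and 0.706 for F-box genes). The ratios to rotated summits were 0.526 for C-type lectins, 0.782 for F-box genes, 1.42 for collagens and 1.43 for nuclear hormone receptors, against 0.212 for chemoreceptors. All genes together had 2519 with a summit against a rotated mean of 773, so rotations do not set a list against other genes. As a share of genes with a summit, the collagen and nuclear hormone receptor calls ended too (ratio to rotated summits 0.437 for both, adjusted permutation p = 0.449 and 0.214), and the collagen call also ended with the 1284 peaks of highest signal (odds ratio 0.446, adjusted exact p = 0.102). The chemoreceptor odds ratio ran from 0.0183 with the shorter promoter window to 0.0543 with the 1284 peaks, the C-type lectin ratio was 0.0521 with the 1284 peaks, and *clec-140* had no summit without replicate 2 and *col-2* none without replicate 1.

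**Figure D3:**
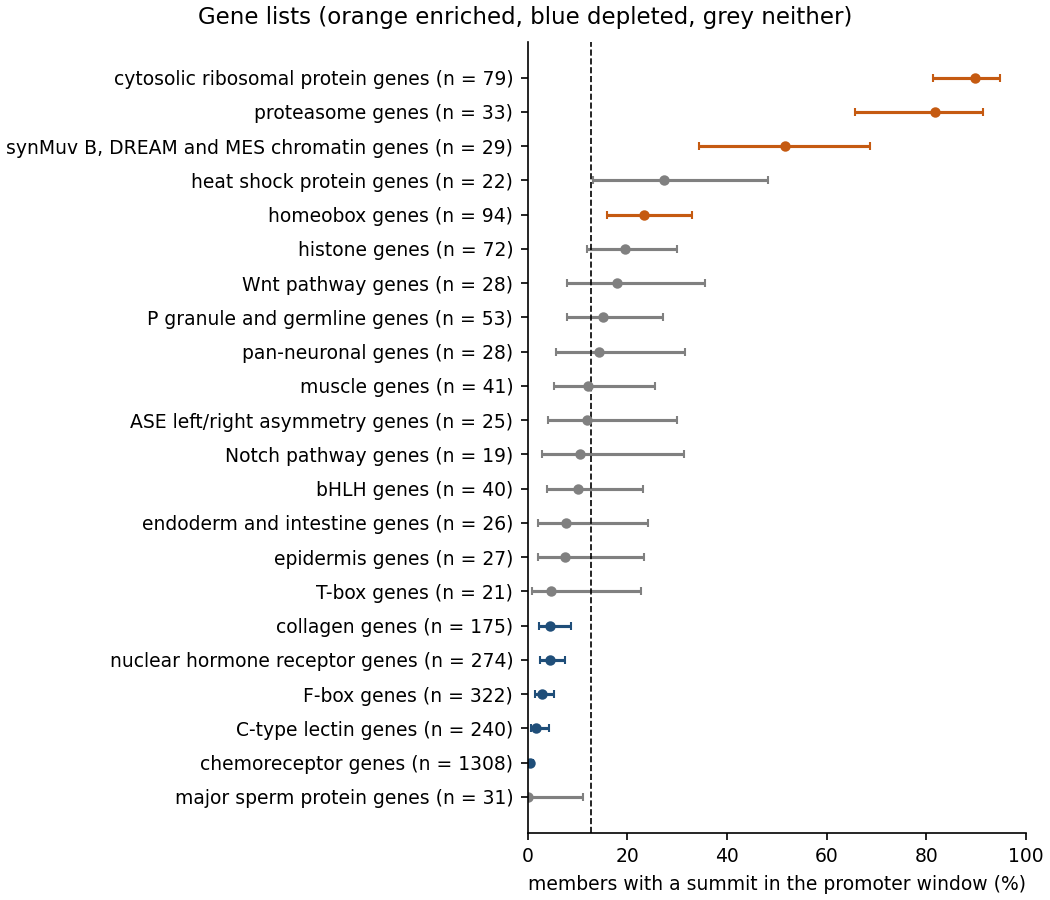
Percent of the members of each of 22 gene lists with an IDR summit in a promoter window (x axis), with 95% Wilson intervals and the number of members as n. The dashed line marks 12.6%, the share of all protein-coding genes. Ribosomal protein genes reached 89.9% and chemoreceptor genes 0.535%.

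The other 13 lists did not pass. Heat shock protein genes had 6 of 22 (adjusted exact p = 0.0998), including *hsp-60* and *hsp-90* at ranks 168 and 211. Histone genes had 14 of 72 (adjusted exact p = 0.194), led by *his-67* and *his-68*, which share the peak of rank 228. Major sperm protein genes had 0 of 31 (upper limit of the interval 11.03%; adjusted exact p = 0.0598). Wnt pathway genes had 5 of 28, with *mig-5*, a Dishevelled homologue, at rank 9 and *sys-1* at rank 958, and Notch pathway genes had 2 of 19, *sel-10* and *hop-1* (adjusted exact p = 0.659 and 1.00). The *mig-5* peak is shared with *cct-1*. P granule and germline genes had 8 of 53, led by *nos-3* and *gld-3* at ranks 60 and 182 (adjusted exact p = 0.782). Among tissue lists, muscle genes had 5 of 41, led by *hlh-1*, the muscle MyoD homologue, and *act-2*. Pan-neuronal genes had 4 of 28, led by *unc-108* and *snb-1*. Endoderm and intestine genes had 2 of 26, *erm-1* and *pha-4*, and epidermis genes 2 of 27, *nhr-25* and *nhr-23* (adjusted exact p between 0.782 and 1.00 for these 4 lists). Without replicate 1, *pha-4* and *nhr-23* had no summit and the endoderm and epidermis lists had 1 member each, with odds ratios of 0.282 and 0.271 against 0.577 and 0.554, and without replicate 2 *erm-1* had none. bHLH genes had 4 of 40, led by *hlh-1* and *mdl-1*, and T-box genes 1 of 21, *tbx-2* (adjusted exact p = 0.941 and 0.782). The heat shock protein list passed with the 1284 peaks of highest signal (adjusted exact p = 0.0115), the histone list with the shorter promoter window (adjusted exact p = 0.0466), and both, with the P granule list, when members were counted against rotated summits. All genes together also exceeded rotated summits there, with 2519 against a mean of 773. As a share of genes with a summit, the ratio to rotated summits was 1.02 for P granule, 2.11 for histone and 2.28 for heat shock protein genes. None of these passed (adjusted permutation p = 0.961, 0.455 and 0.734). The major sperm protein list passed, as depleted, with a promoter window of 2000 bp upstream to 500 bp downstream and in logistic models with the distance to the upstream gene or with promoter GC content.

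The genes of ASE asymmetry, the process in which LSY-2 is best known, had a summit at 3 of 25 members (interval 4.17% to 29.96%; odds ratio 0.945, adjusted exact p = 1.00). These were *lsy-2* itself at rank 42, *lsy-12*, with 2 summits and a best rank of 866, and *unc-37*, the Groucho homologue, at rank 1996. No IDR summit lay in the promoter window of *cog-1*, *die-1*, *che-1*, *lim-6*, *fozi-1*, *nsy-7*, *lin-49*, *lsy-22*, *lsy-27*, *ceh-36*, *tbx-37*, *tbx-38* or *hlh-14*, nor of the receptor guanylyl cyclase genes *gcy-1*, *gcy-3*, *gcy-4*, *gcy-5*, *gcy-6*, *gcy-7*, *gcy-14*, *gcy-20* and *gcy-22*. The microRNA gene *lsy-6* (chromosome V, 10647232 to 10647304) lay 10861 bp from the nearest IDR summit. Without replicate 2, *unc-37* had no summit and 2 members remained (odds ratio 0.624), and without replicate 1 *lin-49* had one (4 members, 1.34). Whole embryos hold few ASE cells, and binding limited to them was not measured separately.

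At its own locus, LSY-2 had 8 IDR summits within 20 kb of *lsy-2* (WBGene00003087, chromosome X, 2089704 to 2093256). The strongest, with a signal of 1424, spanned 2089414 to 2089925 with its summit at -25 bp from the *lsy-2* 5' end, and the next, with a signal of 311, lay in an intron of *lsy-2* from 2090564 to 2090834. The other 6 had signals from 34.2 to 58.4, and those at F49H12.3 and F53B1.3 lay in promoter windows. Rotated summits gave a mean of 0.644 in the same interval (two-sided permutation p = 0.0024), and 99.7% of windows of this length around protein-coding genes held fewer than 8. Around genes of the X chromosome alone, 99.8% of such windows held fewer than 8 and none held more. Around *unc-119*, whose mutation is the strain's background, there were 4 summits against 1.92 for rotated summits (permutation p = 0.320), none in its promoter window. With the 1284 peaks of highest signal, 3 summits remained around *lsy-2*, and with soft-masked summits left out there were 5. Without replicate 1 there were 6 summits around *lsy-2*, and without replicate 2 there were 12.

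**Figure D4:**
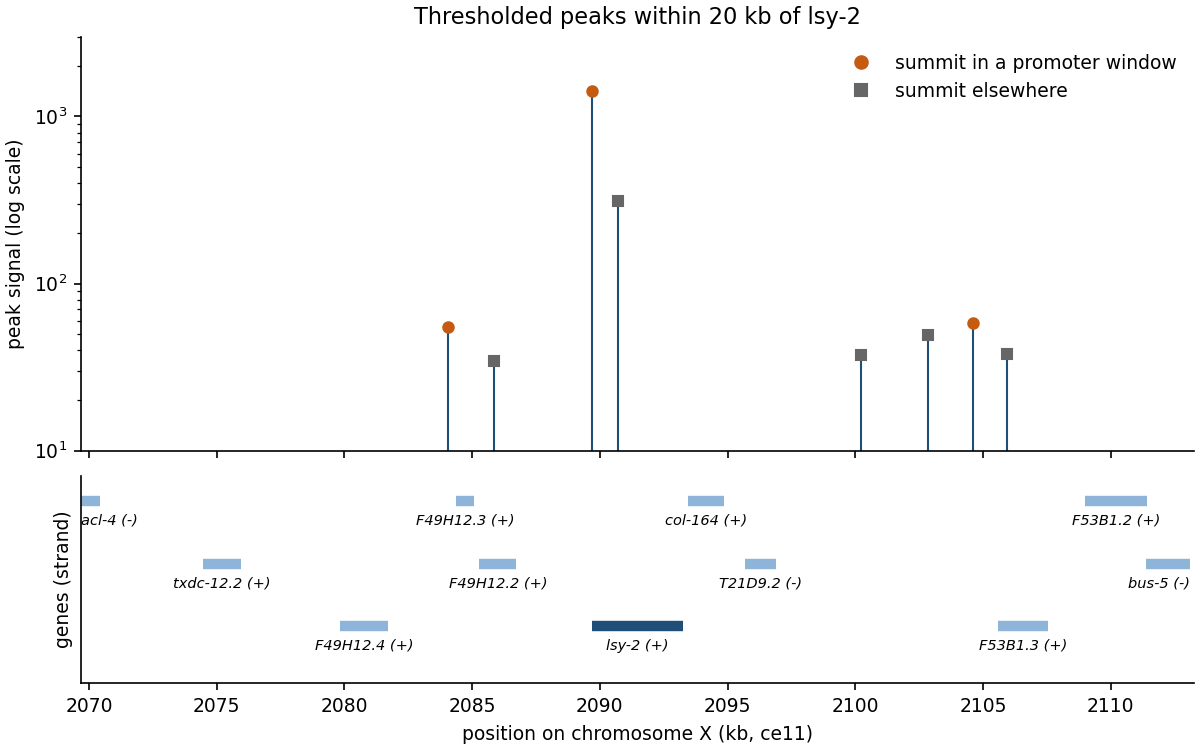
Signal of the IDR peaks (y axis, log scale) against position on chromosome X in kb (x axis, ce11) within 20 kb of *lsy-2*, with circles for summits in promoter windows and squares for others. Bars below mark protein-coding genes with their strand. The peak at the *lsy-2* 5' end has a signal of 1424, and the 6 peaks outside the gene lie between 34.2 and 58.4.

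Noncoding RNA genes were compared with rotated summits. The mitochondrial genome and its 18 IDR summits were included, and shares over nuclear genes alone were not computed. An IDR summit lay within 250 bp of 84 of 634 tRNA genes, or 13.2% (10.8 to 16.1), against 3.33% for rotated summits (two-sided permutation test, adjusted p = 0.0003, from the smallest p that 10000 rotations can give). Small nucleolar RNA genes had 59 of 346, or 17.1% (13.5 to 21.4), against 1.77%, and small nuclear RNA genes 13 of 129, or 10.1% (5.98 to 16.5), against 1.51% (adjusted permutation p = 0.0003 for both). Pseudogenes were below rotated summits, with 26 of 2128, or 1.22%, against 4.33% (adjusted permutation p = 0.0003). MicroRNA genes (9 of 261, adjusted permutation p = 0.0706) and ribosomal RNA genes (2 of 22, adjusted p = 1.00) did not pass. For ribosomal RNA genes rotated summits gave 10.9%, near the observed 9.09%, and all 5 distinct summits near them also lay in protein-coding promoter windows. Rotated summits stay on their chromosome, and the mitochondrial genome held 18 in 13794 bp, so genes there are often hit by rotation alone. The match for ribosomal RNA genes therefore shows nothing about nuclear ones. Protein-coding promoter windows also held 27 of the 77 distinct summits near tRNA genes, 24 of 58 near small nucleolar RNA genes and 9 of 15 near small nuclear RNA genes. With the 1284 peaks of highest signal, the tRNA share was 4.26%.

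The sequence at promoter summits was richer in G and C than control promoter sequence. In windows reaching 50 bp to each side of 1813 nuclear promoter summits the GC content was 46.1% ± 7.70 (SD over windows), against 34.7% ± 8.16 at the same distance from the 5' ends of genes without a summit (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Of 2080 6-mers, counted on both strands, 588 were more frequent at summits and 555 less frequent by Fisher's exact test with adjustment. The 6-mer ACGCGC occurred in 362 of 1813 summit windows and 27 of as many control windows (odds ratio 16.2, adjusted exact p = 3.32e-80). GCGCGC, GAGCGC, CGCGCG and GCGTAC had odds ratios of 14.7, 14.7, 14.2 and 13.7, and occurred in 11.3%, 17.3%, 8.27% and 10.5% of summit windows. Against control windows also matched on GC content, which reached a mean of 44.4%, 333 6-mers were more frequent (284 of the 588 among them) and 551 less frequent, and the odds ratio was 8.22 for ACGCGC, 6.19 for GCGCGC, 5.95 for GAGCGC, 4.53 for CGCGCG and 5.30 for GCGTAC. The windows were not independent where summits lay close together.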

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

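Of the values recomputed for 12 results, 96 kept their direction and side of the threshold, stayed within 1.5 times for counts, or stayed within the 95% interval for the rank correlation, and 8 did not. The promoter share ran from 61.8% to 80.8%, the exon share from 0.701% to 2.10%, the X share from 8.43% to 12.1%, GC content from 40.8% to 49.1%, the tRNA share from 4.26% to 15.1% and the replicate overlap from 45.4% to 77.8%, each on the side of its test reported. The list without an IDR threshold held the same peaks, so it moved nothing and tests nothing, yet its values are among the 96. The count of enriched lists stayed at 4 with the 1284 peaks and with the shorter window, but its members changed. Both settings lost homeobox genes, while the 1284 peaks gained heat shock protein genes and the shorter window gained histone genes. Leaving out a replicate is not possible for the overlap and rank correlation, and for the other 10 results ended none of the calls. With the 1284 peaks of highest signal, there were 1468 genes and 3 summits around lsy-2, and without soft-masked summits (chosen after seeing the data) 5 summits around lsy-2, as fewer peaks entered. The cause was not tested for the following. The rank correlation was 0.765 with the 1284 peaks, and GC-matched controls gave 333 enriched 6-mers. Rotations of summits gave 7 enriched lists and 1 depleted list, in a comparison with random placement that does not set a list against other genes, and their share version (chosen after seeing the data) gave 3 depleted lists. Under rotations the ratio of observed to rotated members was 3.04 for ASE, 2.58 for Notch, 1.14 for T-box, 2.60 for bHLH, 1.42 for collagen, 2.15 for endoderm, 1.15 for epidermis, 2.66 for muscle and 1.43 for nuclear hormone receptor genes, all on the other side of 1 from the odds ratio reported. Under the share version Wnt was 0.974 and pan-neuronal 0.799. Other odds ratios that crossed 1 belonged to lists not past the threshold in either setting. They were ASE 1.10 and pan-neuronal 0.970 with the 1284 peaks; ASE 1.17, Notch 1.01, P granule 0.894 and muscle 1.19 with the shorter window; bHLH 1.12 and epidermis 1.20 with the longer one; muscle 1.04 with upstream distance; ASE 1.02 and histone 0.567 with promoter GC; and ASE 1.21 and Notch 1.04 without soft-masked summits. Leaving out each replicate in turn gave 0.624 to 1.34 for ASE, 0.997 to 1.45 for muscle and 1.01 to 1.03 for bHLH genes, and, with no change of side, 0.282 to 0.598 for endoderm and 0.271 to 0.574 for epidermis genes. Of 97 genes named by rule, the presence of a summit changed for 12 with the shorter window, 8 with the 1284 peaks and 6 without soft-masked summits. It changed for 4 without replicate 1, 3 without replicate 2 and 1 with the longer window. Unknown depth limits what the absence of a summit shows.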

Other observations

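The test of promoter windows around lsy-2 was chosen after its peak coordinates had been seen, the requirement that the below-threshold count pass its bound by more than its counting spread was added after that count was seen, and both tests of 6-mers on separate chromosomes replaced tests of the 5 named 6-mers after those had been seen. The repeat explanations came from a look at sequences in the intron clusters described here. The mitochondrial genome carried 18 IDR peaks in 13794 bp, or 1.30 per kb against 0.0254 per kb in the nuclear genome. All 18 overlapped a peak in each replicate, which shows little about reproducibility. The replicate lists held 27 and 24 peaks in those 13794 bp, and 99.6% of all IDR peaks overlapped a peak of both replicates. The densest 50 kb stretch of chromosome III, from 1894341 to 1940048, held 21 summits, of which 16 lay in introns, and that of chromosome II, from 2202435 to 2250495, held 15, of which 10 lay in introns. The best ranks there were 535 and 403, and the chromosome means were 2.09 and 1.52 summits per 50 kb. In that of chromosome IV, from 4720735 to 4763482, which includes the rpl-20 peak, 0 of 10 summits lay in introns. The densest stretch of chromosome X, from 2084053 to 2105947, held the same 8 summits as the interval around lsy-2. The mean of that chromosome was 0.756 summits per 50 kb. Against GC-matched controls, CCGTAG and ACCGTA, named after their values were seen, had odds ratios of 5.72 and 5.24.

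Peaks clustered around lsy-2, where extra copies of the locus in the transgene are a candidate explanation, since extra copies would raise background reads over the region. The interval held 24 pooled peaks below the IDR threshold, more than 94.4% of windows around protein-coding genes held, and more than 98.3% of those on the X chromosome. The exact Poisson interval of that count, 15.4 to 35.7 peaks, spans the 75.1 to 99.8 percentiles, which includes both bounds set for the test, 95 and 99. Binding at promoters of the locus also stays open, since 37.5% of the summits lay in promoter windows, between the bounds set for it. The transgene and the native locus cannot be told apart, because both carry the same sequence and no control sample was used here.

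Weaker peaks were more often in introns and between genes, with median ranks of 1667 and 1553 against 1143 in promoter windows. Reads shared between copies of a repeat may raise such peaks. The median peak had 0% of its 36-mers repeated in the reference, in introns and between genes alike. That median was also 0% for promoter peaks and random introns, so it does not set the classes apart. Soft-masked sequence held 41.8% of intron summits (36.5 to 47.3), below the 52.2% of random intron positions. It held 18.4% of those between genes (14.9 to 22.4), below 40.2%. These values argue against repeats as the cause for the typical peak of either class, if reads were 36 bp or longer. The read length is unknown, and so is whether reads that map to several places were removed, which would itself lower these shares. Promoter summits also lay below rotated ones in soft-masked share, 19.6% against 34.5%, and exon summits above, 26.1% against 11.9%. A share below random therefore does not by itself set the weaker classes apart from promoter peaks. A part played by repeats in some peaks stays open: 1.93% of intron peaks and 2.23% of those between genes had most of their 36-mers repeated, against 0.492% of promoter peaks and 6.40% of random introns, the upper quartile was 7.54% for intron peaks against 0.942% for random introns, and the soft-masked share of all summits was 15.9% among the 642 of highest signal and 26.5% among the 642 of lowest, a rise not separated from that of the intron share. No biological explanation was tested, as the design has 1 group.

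The 6-mers at promoter summits might follow base composition. To keep the choice of 6-mers apart from their test, 457 6-mers enriched at 1128 summits on chromosomes I, II and III were measured at 685 summits on chromosomes IV, V and X. Their median ratio of frequency at the summit to that 300 bp away in the same promoters was 2.69 (bootstrap 95% interval 2.52 to 2.84), which argues against the composition of the whole promoter as the whole cause. Against GC-matched controls their median odds ratio was 1.64 (1.60 to 1.78), but these controls had a mean GC content of 45.1% against 47.1% at the summits, so the 6-mers and the GC content of the summit window cannot be told apart. A sequence preference of LSY-2 or of other factors at these promoters, and signal common to active promoters in any immunoprecipitation, were not tested, as no control sample was used here.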
